A study of Mus musculus with 12 samples.

How the data were processed

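Total RNA was sequenced from M-MDSC and PMN-MDSC sorted by flow cytometry from spleens of C57BL/6 mice with B16 tumours, untreated (Ctrl) or treated with cyclophosphamide and fludarabine (LD). Per the labels, libraries were made from total RNA with ribosomal RNA depletion. Whether the libraries were stranded is not stated. There are 12 libraries in 4 groups of 3. The labels do not say that replicates are separate animals, so p-values then measure only spread between these samples, which may be technical. They do not say either whether both populations of 1 replicate number came from the same mouse.

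The authors deposited 1 table of 23479 genes in 12 samples, whose unit is a signal, a normalized count made by dividing the reads of each gene by 1 size factor per sample. Every value was a whole multiple of the smallest value of its sample (100% within 0.001 reads), so whole reads were recovered from it. Per the submitters' processing notes, the genome build was mm10 and STAR 2.5.3a, HTSeq 0.6.1 and DESeq2 were used, without their roles or order. All 12 samples were used, and 3377 genes had 0 reads in each. The recovered totals ran from 8906045 to 16242926 reads. These reads carry no molecular identifiers, so they are not independent molecules. Of the 23479 symbols, 23338 matched a RefSeq mouse symbol or synonym of the same build, 21692 of them as the current symbol, and coordinates are from that annotation. Older symbols are kept as deposited (Irg1 is now Acod1, Igj is Jchain and Sc4mol is Msmo1).

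Changes were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a mean over the 12 samples of at least 10 as a minimum (11122 genes), a mean per group, empirical Bayes with a trend and 8 residual degrees of freedom. The spread is pooled over the 4 groups. The comparisons were LD against Ctrl in M-MDSC and in PMN-MDSC, the difference between these changes, and M-MDSC against PMN-MDSC in Ctrl and in LD. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of each comparison, with a threshold of 0.05. On the log scale with 1 added, changes of low genes are understated. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals, and adjusted over the lists of each comparison. The overlap of changed genes was tested with Fisher's exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures.

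The 38 lists were written from general knowledge before the data were examined, as were the comparisons, the minimum level, the threshold, the rule for named genes and the alternatives, except those said to be added later. Of 750 members, 727 matched a gene in the table. Those without a match, among them Ly6g, Ighm, Igkc and the mitochondrial transcripts, were not analysed here, so the mitochondrial list could not be tested and 37 lists were. The lists cover cell division, DNA replication, replication-dependent histones, p53 targets, primary granules, secondary and tertiary granules, mature neutrophil, neutrophil, monocyte, granulocyte-monocyte progenitor, myeloid transcription factors, suppressive function, interferon-stimulated, interferon gamma-inducible, MHC class I, MHC class II and costimulation, IL-6 and STAT3 response, inflammatory cytokines and NF-kappaB targets, chemotaxis and adhesion, ribosome biogenesis, glycolysis, oxidative phosphorylation, cholesterol synthesis and unfolded protein response. Other lists hold markers of B, plasma, T, NK, erythroid, platelet and megakaryocyte, dendritic, macrophage, eosinophil, basophil and mast, melanoma, and stroma and endothelium cells, and nuclear and noncoding RNA. Some lists share genes, so their results are not independent.

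Named genes were chosen by rule. For LD against Ctrl in each population and for M-MDSC against PMN-MDSC in Ctrl, these are the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 100 in the higher group and no overlap between the groups, leaving out predicted genes and clone names. For the difference of the LD changes they are the 5 largest each way, where overlap was allowed. Each list adds up to 4 members past the threshold with the smallest adjusted p, or up to 2 as values where none passed. Arg1, Nos2, S100a8, S100a9, Cd274, Il6ra, Socs3, Mki67, Ly6c2, Ly6g, Ccr2 and Cxcr2 were named in any case. Genes in the list of shared changes, Ltf and Ngp in PMN-MDSC, and genes of the closing tests were chosen after their values were seen. Some genes that the rule names are not reported here.

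Alternatives were a pseudocount of 0.5 or 8, no minimum level or a mean of at least 50, TMM and upper-quartile scaling, sample weights, robust empirical Bayes, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on the recovered reads, a block by replicate number or by presumed animal, each library left out in turn, each population fitted alone, a change of at least 1 on the log2 scale, an adjusted p under 0.01, and the estimated correlation. Sample weights by group, reads thinned to the lowest total and leaving out both LD libraries numbered 001 were added after the data were seen.

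The method was tested on simulated data with known changes, using means and dispersions estimated from these libraries. In M-MDSC 69.4% of 2-fold and 92.9% of 4-fold changes were recovered and 8.57% of the calls were false. In PMN-MDSC these were 44.0%, 84.0% and 2.29%. Each simulation gave all groups the same dispersions, estimated from the population tested. In the data, PMN-MDSC LD libraries varied more (residual variance 0.437, against 0.129 to 0.206 in the other groups). The shares of recovered changes and false calls therefore do not cover this unequal spread. A list raised in the simulation gave camera p of 8.1e-65 and 1.3e-58, and an unchanged list 0.553 and 0.781. The raised list was made of genes raised in the simulation, so its small p-values were set by design. Only means and dispersions were taken from these libraries, so the simulation does not test camera on genes that move together. It therefore does not decide between the preset and the estimated correlation.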

Results

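Total RNA was sequenced from 2 populations of myeloid-derived suppressor cells, immature myeloid cells that build up in tumour-bearing animals and restrain T cells. Monocytic cells (M-MDSC) and polymorphonuclear, neutrophil-like cells (PMN-MDSC) were sorted from spleens of C57BL/6 mice with B16 melanomas. Mice were either untreated (Ctrl) or lymphodepleted (LD) with cyclophosphamide, an alkylating drug, and fludarabine, a purine analogue, and spleens were taken 7 days after treatment. The 12 libraries form 4 groups of 3 (M-MDSC Ctrl, M-MDSC LD, PMN-MDSC Ctrl and PMN-MDSC LD), numbered 001 to 003 within each group. The reads assigned to genes came to 13932809, 9821005 and 16242926 in M-MDSC Ctrl (replicates 001, 002 and 003) and to 11833775, 10683962 and 9185223 in M-MDSC LD. They came to 14194551, 15810717 and 8906045 in PMN-MDSC Ctrl and to 10140572, 10175233 and 11273031 in PMN-MDSC LD. Levels are normalized counts, given as mean ± SD with n = 3 libraries per group. Changes are log2 differences ± SE from limma, and a fold change is that fitted log2 difference turned back to a ratio, so it is not the ratio of the means printed beside it. They were tested over 11122 genes with Benjamini-Hochberg adjusted p.

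Cell type separated the libraries more than treatment did. The first principal component held 80.9% of the variance, with M-MDSC libraries between -116.9 and -96.7 and PMN-MDSC libraries between 95.8 and 126.1. The second held 4.59% and placed the Ctrl libraries of both populations between -30 and -18.7 and the LD libraries between 9.2 and 42.7. LD replicate 001 lay farthest from Ctrl in both populations, at 42.7 in M-MDSC and 41.5 in PMN-MDSC. The same libraries held the most Mki67 RNA of their groups. Mki67, a marker of cycling cells, read 8133 in M-MDSC LD replicate 001 against 2434.4 and 3200.8 in replicates 002 and 003, and 6242 in PMN-MDSC LD replicate 001 against 1260.5 and 2024.9.

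**Figure D1:**
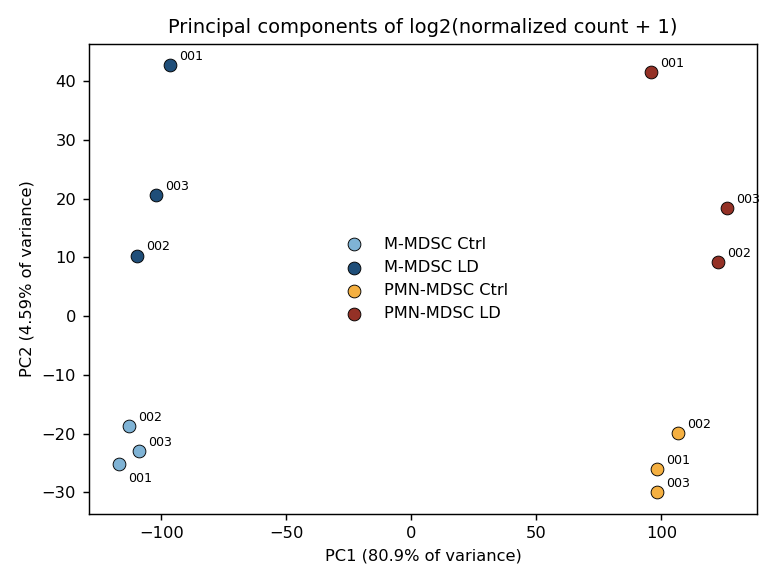
Principal components of log2(normalized count + 1) over 11122 genes, with PC1 on the x axis (80.9% of variance), PC2 on the y axis (4.59%) and 1 point per library labelled with its replicate number. M-MDSC libraries lie on the left (-116.9 to -96.7) and PMN-MDSC libraries on the right (95.8 to 126.1), and LD libraries (9.2 to 42.7) lie above Ctrl libraries (-30 to -18.7).

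How far the sorted populations differed was asked first in untreated mice. M-MDSCs held 35.8-fold more Ccr2 than PMN-MDSCs (12866.2 ± 950.2 against 374.4 ± 128.9), which encodes the chemokine receptor that brings monocytes out of bone marrow. They also held 42.7-fold more F13a1, 36.3-fold more Fn1 (fibronectin) and 22.3-fold more Irf8, a transcription factor of monocyte development. PMN-MDSCs held more Retnlg (8231.8 ± 1861.5 against 9.0 ± 7.2), a neutrophil-secreted protein, more Csf3r, the G-CSF receptor (160134.2 ± 8292.6 against 4556.9 in M-MDSC), and more Il1b (33527.8 ± 2814.3 against 284.5). S100a9, a calprotectin subunit, read 97874.9 ± 7783.5 in PMN-MDSC and 901.8 ± 177.5 in M-MDSC, a log2 difference of -6.78 ± 0.41 (limma adjusted p = 1.8e-09). Cd274, which encodes PD-L1, was likewise higher in PMN-MDSC (1481.8 ± 84.4 against 204.5 ± 28.9, a difference of -2.86 ± 0.17 with limma adjusted p = 1.7e-09).

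Of the 11122 genes, 4317 were higher in M-MDSC and 4090 in PMN-MDSC (8407, 75.6%). Other large differences toward M-MDSC were in Rem1, Stxbp6, Eng, Vcan, Shb, Plcb1 and Met, with log2 differences of 5.36 to 6.61, and for Eng and Stxbp6 these moved by over 1.5 times in fold when 1 PMN-MDSC Ctrl library was left out (Eng 4.99 without replicate 001 and 6.41 without 002, Stxbp6 6.71 without 003). Toward PMN-MDSC they were in Mmp9, Cxcr2, Dhrs9, Asprv1, Steap4, H2-Q10 and Amer2, with log2 differences of -11.01 to -9.48, for which M-MDSC levels were near 0 and 1 M-MDSC Ctrl library moved the fold for Mmp9 (-9.91 without replicate 001 and -11.68 without 002), Cxcr2 (-9.73 without 001) and Steap4 (-8.99 without 001). H2-Q10 has close relatives in the same gene family, so the reads behind it are uncertain. Of 28 monocyte genes, 23 were higher in M-MDSC and 3 in PMN-MDSC (camera adjusted p = 7.4e-06), and all 24 mature neutrophil genes were higher in PMN-MDSC (camera adjusted p = 2.5e-11). Adjusted over the list alone, the counts were the same for both lists. Toward M-MDSC lay ribosome biogenesis (21 of 24 higher, 1 lower, camera adjusted p = 9.3e-05), oxidative phosphorylation (22 of 27, 6.2e-05), cholesterol synthesis (16 of 19, 2 lower, 0.00273) and MHC class II and costimulation (9 of 14, 1 lower, 0.0347). The last was lost with upper-quartile scaling (0.0657), robust empirical Bayes (0.0525) and DESeq2 (0.058). Toward PMN-MDSC lay the neutrophil list (21 of 22, camera adjusted p = 2.9e-08), secondary and tertiary granules (17 of 20, 3 higher in M-MDSC, 6.2e-05), suppressive function (20 of 26, 4 higher in M-MDSC, 4.0e-04), glycolysis (13 of 19, 1 higher in M-MDSC, 0.00163), IL-6 and STAT3 response (16 of 23, 6 higher in M-MDSC, 0.0214) and chemotaxis and adhesion (15 of 23, 6 higher in M-MDSC, 0.0413). Chemotaxis and adhesion was lost without PMN-MDSC Ctrl replicate 001 (camera adjusted p = 0.0648) and with a minimum mean of 50 (0.0911). None of these 12 lists passed with an estimated correlation, where the smallest was suppressive function at adjusted p = 0.0818 with an estimated correlation.

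In LD mice, 4310 genes were higher in M-MDSC and 4013 in PMN-MDSC. Monocyte genes (24 of 28 higher in M-MDSC, 3 lower, camera adjusted p = 1.4e-06) and mature neutrophil genes (24 of 24 higher in PMN-MDSC, camera adjusted p = 1.6e-11) differed between the populations in LD mice as well. MHC class II and costimulation had 11 of 14 members higher in M-MDSC LD and 1 lower (camera adjusted p = 0.00191), with a median log2 difference of 3.86. Of 37 lists, 11 passed with the preset correlation and 0 with an estimated one, where the smallest was adjusted p = 0.156 with an estimated correlation.

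What lymphodepletion left behind in M-MDSCs was asked next. Genes of neutrophil granules and of the cell cycle were higher in M-MDSCs of LD mice. Ltf, which encodes lactoferrin (mm10 chromosome 9, 111019292 to 111042766), rose 11.8-fold from 619.3 ± 91.1 to 8748.6 ± 6098.3 (log2 change 3.56 ± 0.36, limma adjusted p = 1.6e-04). Ngp, another granule protein, rose by a log2 change of 3.32 ± 0.38 and Ccna2, a cyclin of S and G2 phases, rose 9.85-fold from 31.2 ± 6.6 to 358.5 ± 238.6 (log2 change 3.30 ± 0.54, limma adjusted p = 0.00311). Ifit2, an interferon-stimulated gene, rose 2.21-fold from 657.7 ± 68.0 to 1448.1 ± 74.8, and H2-Eb1, an MHC class II chain, rose 3.13-fold from 568.0 ± 121.1 to 1753.0 ± 105.6. Thbs1 (thrombospondin 1) fell from 933.1 ± 340.4 to 189.2 ± 25.4, a change of -2.24 ± 0.36 (limma adjusted p = 0.00302).

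In all, 283 genes rose and 52 fell in M-MDSC (335 of 11122, 3.01%), of which 222 and 8 changed at least 2-fold. The count was 192 without M-MDSC Ctrl replicate 001, 199 without M-MDSC Ctrl replicate 003, 217 without M-MDSC LD replicate 003 and 549 without PMN-MDSC LD replicate 001, since the 4 groups share 1 estimate of the spread. Of 75 named genes called in M-MDSC, 45 passed whichever library was left out. Besides Ltf, the largest rises were in Mpo, Elane, Kif18b (a mitotic kinesin), Sept5, Itgb2l, Hist1h3b and Camp (cathelicidin), with log2 changes of 3.52 to 4.22. Kif18b moved to 3.30 without M-MDSC LD replicate 001 and to 4.53 without replicate 002. Besides Thbs1, the largest falls were in Igj (the immunoglobulin J chain, 184.2 ± 133.3 to 1.1 ± 1.0), Adam19, Amica1, Abca9, Mmp8, Arrdc4 and Bst1, with log2 changes of -6.33 to -0.81. Mmp8 no longer passed without M-MDSC Ctrl replicate 002 (limma adjusted p = 0.0524) or LD replicate 003 (0.0546), and Abca9 without Ctrl replicate 001 (0.0583) or LD replicate 001 (0.054).

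Of 25 cell division genes, 16 rose and 9 did not pass in M-MDSC, and 23 rose when adjusted over the list alone (median log2 change 2.33, camera adjusted p = 2.9e-26, and adjusted p = 0.0802 with an estimated correlation). Examples are Prc1 (2.79 ± 0.45), Hmmr (3.20 ± 0.55) and Ube2c (2.33 ± 0.44). Mki67 rose 4.8-fold from 834.8 ± 103.8 to 4589.4 ± 3092.7 (limma adjusted p = 0.0145) but no longer passed without Ctrl replicate 002 (0.0575), Ctrl replicate 003 (0.0608) or LD replicate 001 (0.054). Of 14 replication-dependent histones, 6 rose and 8 did not pass, and 12 rose adjusted over the list alone (median 1.52, camera adjusted p = 2.4e-15, and adjusted p = 0.0802 with an estimated correlation). Histone genes are close copies of one another, so the reads of single copies are uncertain. Of 27 DNA replication genes, 1 rose (Mcm10, a replication fork factor, 1.57, limma adjusted p = 0.0257) and 26 did not pass, while 13 rose adjusted over the list alone (median 1.16, camera adjusted p = 1.1e-12, and adjusted p = 0.183 with an estimated correlation). Mcm10 no longer passed in 3 of 12 fits that left out 1 library, with the highest limma adjusted p without M-MDSC LD replicate 001 (0.114). Of 19 p53 targets, limma called 0 (1 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with a camera adjusted p of 0.761.

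Granule and progenitor genes rose in the same libraries. Of 20 secondary and tertiary granule genes, 9 rose, 1 fell (Mmp8) and 10 did not pass, and 11 rose and 1 fell adjusted over the list alone (median 1.07, camera adjusted p = 1.5e-14, and adjusted p = 0.072 with an estimated correlation). Of 10 primary granule genes, 5 rose and 5 did not pass, and 6 rose and 1 fell adjusted over the list alone (median 2.07, camera adjusted p = 4.9e-06, and adjusted p = 0.103 with an estimated correlation). Mpo, myeloperoxidase (chromosome 11, 87793784 to 87804412), rose from 93.5 ± 23.4 to 2190.8 ± 1903.5 (4.22 ± 0.99, limma adjusted p = 0.0306), and Elane, neutrophil elastase, from 34.7 ± 6.7 to 778.2 ± 764.6 (4.01 ± 0.78, limma adjusted p = 0.0105). Mpo no longer passed without any 1 of the 3 Ctrl libraries (0.105, 0.102 and 0.0769) or without LD replicate 001 (3.55, 0.126) or 003 (0.0694), and Elane without Ctrl replicate 001 (0.0525) or LD replicate 001 (3.24, 0.057). Granulocyte-monocyte progenitors express both genes as well. Of 13 granulocyte-monocyte progenitor genes, 4 rose (Myb 2.25 ± 0.42, Kit 2.47 ± 0.46, Cd63 and Erg) and 9 did not pass, and 7 rose adjusted over the list alone (median 1.01, camera adjusted p = 8.9e-07, and adjusted p = 0.0607 with an estimated correlation). Cd63 moved from 2.71 to 1.98 without M-MDSC LD replicate 001 and to 3.51 without 002, and Erg from 2.79 to 2.12 without 001.

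The neutrophil list shares Ltf, Ngp, Camp, Lcn2, Cd177, Mmp8, Mmp9, Mmp25, Padi4 and Ltb4r1 with the secondary and tertiary granule list. Cebpe and Gfi1 are also among the myeloid transcription factors. In part through these shared genes, the neutrophil list moved in the same direction. Of its 22 measured genes, 11 rose, 1 fell and 10 did not pass in M-MDSC, and 14 rose and 1 fell adjusted over the list alone (median 1.82, camera adjusted p = 2.5e-16, and adjusted p = 0.0607 with an estimated correlation). S100a9 rose 10.4-fold from 901.8 ± 177.5 to 12098.1 ± 10473.1 (3.38 ± 0.41, limma adjusted p = 6.3e-04) and S100a8 8.83-fold (3.14 ± 0.43, limma adjusted p = 0.00101). Without LD replicate 001 these changes were 2.70 and 2.42, and without LD replicate 002 they were 3.99 and 3.79. Of 24 mature neutrophil genes, 4 rose, 2 fell and 18 did not pass (median 0.08, camera adjusted p = 0.0819), with 5 and 2 adjusted over the list alone. The list passed without a minimum level (0.00826) and by edgeR (0.0437). Irg1, which makes itaconate, rose (2.74 ± 0.31, limma adjusted p = 3.0e-04), while Cxcr2, a chemokine receptor of mature neutrophils, read 25.3 ± 14.8 in Ctrl and 56.6 in LD (limma adjusted p = 0.346). Of 23 myeloid transcription factors, 5 rose and 18 did not pass, and 5 rose and 1 fell adjusted over the list alone (median 0.23, camera adjusted p = 6.9e-04, and adjusted p = 0.0607 with an estimated correlation). Cebpe, which drives granule gene expression, rose 5.39-fold (2.43 ± 0.33) and Gfi1, a repressor in neutrophil development, rose from 5.8 ± 3.4 to 78.7 ± 56.0 (3.50 ± 0.54). Of 28 monocyte genes, 3 rose and 25 did not pass, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.162). The list passed with sample weights (0.0465) and without a minimum level (0.0207). Cd300e, a monocyte receptor, rose 6.06-fold, whereas Ccr2 (12866.2 ± 950.2 and 10988.9) and Ly6c2 (1559.4 ± 235.2 and 2195.8 ± 218.3) did not pass (limma adjusted p = 0.865 and 0.123).

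Interferon and antigen-presentation genes rose in M-MDSC. Of 32 interferon-stimulated genes, 10 rose and 22 did not pass, and 11 rose adjusted over the list alone (median 0.30, camera adjusted p = 1.7e-14, and adjusted p = 0.0802 with an estimated correlation). Besides Ifit2 (1.14 ± 0.10, limma adjusted p = 8.3e-05) these included Ifit3 (1.11 ± 0.16) and Rsad2 (1 ± 0.15). Of 18 interferon gamma-inducible genes, 4 rose and 14 did not pass, and 8 rose adjusted over the list alone (median 0.32, camera adjusted p = 6.1e-10). This was the only list past the threshold with an estimated correlation in M-MDSC (adjusted p = 0.0219 with an estimated correlation). Cxcl10, a chemokine that draws T cells, rose 3.71-fold from 47.3 ± 22 to 168.7 ± 24.5, and Gbp4, a guanylate-binding protein, rose from 63.0 to 199.4. Both passed whichever library was left out. The other 2 did not, and Cxcl9 (2.14) was lost without Ctrl replicate 001 (0.0532), 002 (0.0875) or 003 (0.0678) or LD replicate 001 (0.0995) or 003 (0.0554). Of 14 MHC class I genes, 2 rose (H2-K1, 0.72 ± 0.11, and H2-Q4, whose reads are uncertain between close copies) and 12 did not pass, and 7 rose adjusted over the list alone (median 0.29, camera adjusted p = 4.0e-08, and adjusted p = 0.0726 with an estimated correlation). Of 14 MHC class II and costimulation genes, 3 rose and 11 did not pass, and 5 rose adjusted over the list alone (median 0.50, camera adjusted p = 7.8e-04, and adjusted p = 0.23 with an estimated correlation). The other members that rose were H2-Aa and Cd74, the invariant chain (4771.7 ± 526.7 to 9969.3 ± 1495.5, 1.06 ± 0.24, limma adjusted p = 0.0283). Cd74 no longer passed in 5 of the 12 fits that left out 1 library (highest limma adjusted p 0.112, without LD replicate 003) and H2-Aa in 4 (0.0829, without Ctrl replicate 002).

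Genes of suppressor function and inflammation gave a mixed picture in M-MDSC. Of 26 suppressive function genes, 5 rose and 21 did not pass, and 6 rose and 2 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.04, and adjusted p = 0.0907 with an estimated correlation). The list was lost without M-MDSC Ctrl replicate 001 (0.153), M-MDSC LD replicate 003 (0.121) or PMN-MDSC Ctrl replicate 003 (0.061), and also with a block by replicate number (0.0535) and robust empirical Bayes (0.0826). Its members that rose included S100a8, S100a9, Vegfa (8.6 ± 6.5 to 95.1 ± 80.0, a growth factor for vessels) and Cd274, which rose 1.86-fold from 204.5 ± 28.9 to 388.9 ± 118.3 (0.89 ± 0.17, limma adjusted p = 0.0104). Cd274 read 0.0506 without Ctrl replicate 002 and 0.059 when the M-MDSC libraries were fitted alone, a fit in which the list did not pass either (0.0902), and the Vegfa change of 3.18 was 2.52 without LD replicate 001 and 3.87 without 002. For S100a8 and S100a9, leaving out LD replicate 001 gave 2.42 and 2.70 and leaving out 002 gave 3.79 and 3.99. Arg1 (4.7 ± 2.7 and 1.4 ± 2.5) and Nos2 (1.5 and 2.7), enzymes that deplete arginine or make nitric oxide, were under the minimum level for testing. Of 20 inflammatory cytokines and NF-kappaB targets, 4 rose and 16 did not pass, and 5 rose adjusted over the list alone (median 0.31, camera adjusted p = 2.8e-06, and adjusted p = 0.0802 with an estimated correlation). Il1rn, the IL-1 receptor antagonist, rose 2.26-fold from 118.3 ± 6.9 to 269.8 ± 28.1. Of 23 IL-6 and STAT3 response genes, 2 rose and 21 did not pass, with 2 adjusted over the list alone (camera adjusted p = 0.845), and neither Il6ra (-0.11, limma adjusted p = 0.704) nor Socs3 (-0.05, 0.982) passed.

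Among metabolic lists in M-MDSC, 2 of 19 glycolysis genes rose and 17 did not pass, with 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.00321, and adjusted p = 0.271 with an estimated correlation). Slc16a3, a lactate exporter, rose from 704.3 ± 33.4 to 1089.2 ± 48.6. The cholesterol synthesis list passed (median 0.34, camera adjusted p = 5.8e-05, and adjusted p = 0.0802 with an estimated correlation) although limma called 0 of its 19 members over all genes (7 at an unadjusted p under 0.05, 3 by edgeR, 4 by DESeq2) and 3 rose adjusted over the list alone. Limma called 0 members of ribosome biogenesis (24 genes, camera adjusted p = 0.927), oxidative phosphorylation (27 genes, 0.927) and unfolded protein response (22 genes, 0.723). At an unadjusted p under 0.05 these held 0, 0 and 5 members, by edgeR 0, 0 and 1, and by DESeq2 0, 0 and 2. Of 23 chemotaxis and adhesion genes, 1 rose (Ccrl2), 1 fell and 21 did not pass, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.364). Ccrl2 no longer passed in 5 of 12 fits that left out 1 library (highest limma adjusted p 0.112, without LD replicate 003).

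Markers of other cells moved in the same M-MDSC libraries. The ribosomal RNA precursor Rn45s made up 8.82% to 10.49% of reads in Ctrl and 6.02% to 8.2% in LD, without overlap, which chance gives in 10% of such groups. Of 16 macrophage genes, 5 rose and 11 did not pass, and 9 rose and 1 fell adjusted over the list alone (median 1.05, camera adjusted p = 2.7e-05, and adjusted p = 0.0607 with an estimated correlation). Axl, a receptor for dying cells, rose from 433.1 ± 53.4 to 1401.9 ± 130.5 (1.70 ± 0.33, limma adjusted p = 0.0104, and 0.0545 without Ctrl replicate 001), and C1qa read 11.4 ± 3.1 and 49.7 ± 12.4 (limma adjusted p = 0.0396, lost in 7 of 12 fits that left out 1 library, with 0.158 without Ctrl replicate 003). Hdc, the histidine decarboxylase and the only measured gene of the basophil and mast cell list, rose 5.45-fold from 29.7 to 186 (camera adjusted p = 0.00147, and adjusted p = 0.0607 with an estimated correlation). It read 14629.7 in PMN-MDSC Ctrl, so its rise need not come from basophils or mast cells. Of 4 eosinophil genes 1 rose (Cebpe, which neutrophil precursors express as well) and 3 did not pass, with 1 adjusted over the list alone (median 0.74, camera adjusted p = 0.0095, adjusted p = 0.191 with an estimated correlation, and 0.0585 without LD replicate 001, where the median was 0.22, against 1.47 without 002). The NK cell list passed (3 genes, median 2.47, camera adjusted p = 0.0134, and adjusted p = 0.192 with an estimated correlation) with 2 members adjusted over the list alone and 0 called by limma over all genes (2 at an unadjusted p under 0.05, 1 by edgeR, 0 by DESeq2), and was lost without Ctrl replicate 001 (0.058) or LD replicate 001 (0.052). The erythroid list held 1 measured gene, Tfrc, the transferrin receptor of dividing cells (1.69, camera adjusted p = 0.0269, adjusted p = 0.0995 with an estimated correlation, and 0.0627 without LD replicate 001), whose limma adjusted p of 0.0454 ended in 9 of 12 fits that left out 1 library (0.166 without LD replicate 001). Of the plasma cell list, Igj fell and 3 members did not pass (camera adjusted p = 0.206). Of the B cell list, Cd37 rose (0.37, limma adjusted p = 0.0463, lost in 10 of 12 fits that left out 1 library, with 0.158 without Ctrl replicate 001) and 4 members did not pass (camera adjusted p = 0.761). Of 12 dendritic cell genes, Itgax, an integrin, rose (0.88 ± 0.16) and 11 did not pass (0.761). T cell (0.987), platelet and megakaryocyte (0.608), melanoma (0.191), stroma and endothelium (0.121) and nuclear and noncoding RNA (0.641) did not pass, and limma called 0 of their 3, 6, 2, 3 and 8 members. At an unadjusted p under 0.05, 1 stroma and endothelium gene and 0 of the others stood, and edgeR and DESeq2 called 0 in each.

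**Figure D2:**
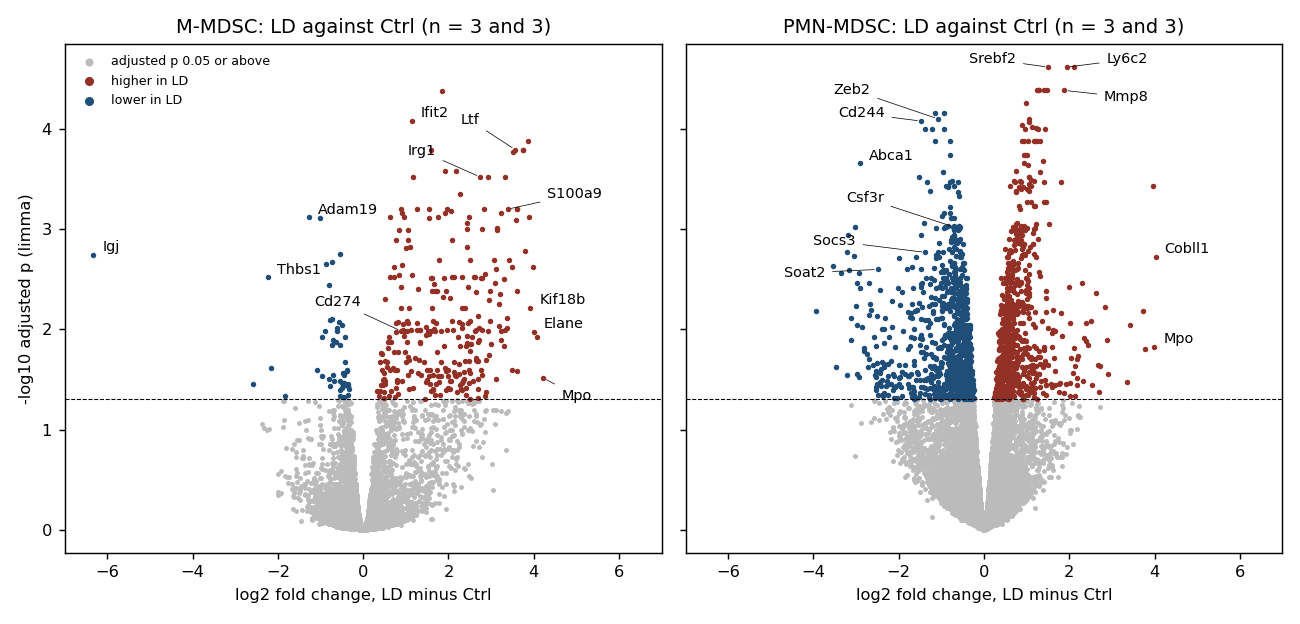
Log2 change (LD minus Ctrl, x axis) against -log10 of the limma adjusted p (y axis) for 11122 genes in M-MDSC (left, 283 higher in red and 52 lower in blue) and PMN-MDSC (right, 798 higher and 947 lower), with 3 libraries per group. Genes in grey lie under the dashed line at an adjusted p of 0.05.

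How PMN-MDSCs differed after lymphodepletion was asked in the same way. Granule genes and genes of cholesterol supply were higher in PMN-MDSCs of LD mice, and the cholesterol exporter Abca1 was lower. Mmp8, neutrophil collagenase (chromosome 9, 7558429 to 7568486), rose 3.69-fold from 8100.0 ± 176.8 to 30688.0 ± 8298.1 (1.88 ± 0.17, limma adjusted p = 4.1e-05). Ly6c2, a surface antigen of monocytes and immature myeloid cells, rose 3.83-fold from 523.0 ± 127.1 to 1974.7 ± 215.0 (1.94 ± 0.16, limma adjusted p = 2.4e-05). Srebf2, the regulator of cholesterol synthesis genes, rose 2.85-fold from 588.1 ± 13.7 to 1691.0 ± 236.6, and Abca1 (chromosome 4, 53030789 to 53159988) fell 7.56-fold from 670.4 ± 126.7 to 101.8 ± 71.4 (-2.92 ± 0.35, limma adjusted p = 2.2e-04). Socs3, a feedback inhibitor that STAT3 induces, fell 2.6-fold from 7261.7 ± 563.8 to 2917.1 ± 1110.9 (-1.38 ± 0.23, limma adjusted p = 0.0017).

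In PMN-MDSC, 798 genes rose and 947 fell (1745 of 11122, 15.7%), of which 188 and 258 changed at least 2-fold. The count was 1101 without PMN-MDSC Ctrl replicate 002 and 890 without PMN-MDSC Ctrl replicate 003. Libraries varied most in PMN-MDSC LD (residual variance 0.437, against 0.129 to 0.206 in the other groups), so the pooled spread is too small for that group. With weights by group 56.1% of the 1745 calls were kept, and with the PMN-MDSC libraries fitted alone 65.8%. Of 94 named genes called in PMN-MDSC, 45 passed whichever library was left out. The largest rises were in Cobll1 (7.4 ± 7.3 to 120.9 ± 66.7), Mpo, Lyve1, Ptpn3, Prok2, Stfa1, Tgm3 and Gpr27, with log2 changes of 2.44 to 4.02. Of these, Cobll1, Lyve1 and Tgm3 passed whichever library was left out, with Cobll1 at 4.70 without Ctrl replicate 002 and Tgm3 at 3.24 without LD replicate 001. The others each failed without 1 to 4 of the PMN-MDSC libraries, with the highest limma adjusted p at 0.0672 for Mpo (without Ctrl replicate 002), 0.105 for Ptpn3 (LD 003), 0.0666 for Prok2 (Ctrl 003), 0.0695 for Stfa1 (Ctrl 001), a gene with close copies, and 0.0654 for Gpr27 (LD 003). The largest falls were in Abca1, Soat2 (which esterifies cholesterol, 1108.3 ± 93.9 to 207.7 ± 87.5), Wfdc17, Klf11, Slc15a2, Mir24-2, Piwil2 and Slc12a2, with log2 changes of -2.92 to -1.66. Wfdc17 (0.0526, LD 003), Slc15a2 (0.115, LD 003) and Piwil2 (0.0693, Ctrl 003) did not pass without the library named, and without LD replicate 001 Klf11 moved from -2.17 to -2.91 and Wfdc17 from -2.23 to -3.19.

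Granule genes rose together in PMN-MDSC. Of 20 secondary and tertiary granule genes, 14 rose and 6 did not pass, and 18 rose adjusted over the list alone (median 1.15, camera adjusted p = 1.4e-13, and adjusted p = 0.268 with an estimated correlation). They included Lyz2, lysozyme (26664.5 ± 1837.9 to 71700.6 ± 3807.1, 1.43 ± 0.16), Cybb, the catalytic NADPH oxidase subunit (1.20 ± 0.14), Anxa1 (1.01 ± 0.12), Ltf (1.29 ± 0.36) and Ngp (1.39 ± 0.38). Of 22 neutrophil genes, some of them in the secondary and tertiary granule list as well, 12 rose, 1 fell (Csf3r) and 9 did not pass, and 16 rose and 1 fell adjusted over the list alone (median 1.24, camera adjusted p = 8.0e-08, and adjusted p = 0.464 with an estimated correlation). Csf3r fell from 160134.2 ± 8292.6 to 98750.7 ± 3030.9 (-0.70 ± 0.10, limma adjusted p = 9.5e-04). S100a8 (36382.6 ± 1265.5 and 85207.0 ± 2071.2, limma adjusted p = 0.0693) and S100a9 (97874.9 ± 7783.5 and 231758.6 ± 8236.5, 0.0553) did not pass. Fitted on the PMN-MDSC libraries alone, where the wide spread of the M-MDSC LD libraries plays no part, they gave limma adjusted p of 3.0e-04 and 0.00168. Of 10 primary granule genes, 5 rose and 5 did not pass, with 5 adjusted over the list alone (median 0.82, camera adjusted p = 0.00448, adjusted p = 0.464 with an estimated correlation, and 0.059 without LD replicate 001). Elane read 0.3 ± 0.5 in Ctrl and 24.8 ± 28.1 in LD, and Mpo 3.3 ± 4.1 and 108.9 ± 147.8 (limma adjusted p = 0.015, and 0.0672 without Ctrl replicate 002). The Mpo change of 3.99 was 4.78 without Ctrl replicate 003, 2.72 without LD replicate 001 and 5.14 without LD replicate 002, and the Elane change of 3.72 was 2.80 without LD replicate 001 and 4.54 without LD replicate 003. Of 24 mature neutrophil genes, 3 rose, 3 fell and 18 did not pass, with the same counts adjusted over the list alone (median 0.06, camera adjusted p = 0.793).

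Cholesterol synthesis and glycolysis genes rose in PMN-MDSC. Of 19 cholesterol synthesis genes, 10 rose and 9 did not pass, and 11 rose adjusted over the list alone (median 0.94, camera adjusted p = 1.9e-08, and adjusted p = 0.155 with an estimated correlation). Besides Srebf2 they included Sc4mol, a sterol methyl oxidase (1.26 ± 0.14), and Hmgcs1 (0.88 ± 0.14). Of 19 glycolysis genes, 9 rose, 2 fell and 8 did not pass, with the same counts adjusted over the list alone (median 0.40, camera adjusted p = 0.00706, and adjusted p = 0.495 with an estimated correlation). Gapdh rose 1.82-fold and Pgk1 1.77-fold. Of 27 oxidative phosphorylation genes, 4 rose and 23 did not pass, and 6 rose adjusted over the list alone (median 0.25, camera adjusted p = 5.3e-04, and adjusted p = 0.464 with an estimated correlation). Uqcrc1, a complex III subunit, rose from 475.2 ± 30.5 to 708.9 ± 28.0 and passed whichever library was left out. The other 3 did not, with the highest limma adjusted p at 0.0661 for Atp5a1 (without Ctrl replicate 003, its only failure), 0.125 for Cox6c (without LD replicate 002, 1 of 6 failures) and 0.127 for Cox7b (without LD replicate 003, 1 of 5).

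Some IL-6 and STAT3 response genes fell in PMN-MDSC. Of 23, 5 fell and 18 did not pass, and 6 fell adjusted over the list alone (median -0.20, camera adjusted p = 0.00448, and adjusted p = 0.464 with an estimated correlation). Besides Socs3 they included Il10ra, a receptor that signals through STAT3 (-0.81 ± 0.14), the survival gene Mcl1 (45566.0 ± 275.4 to 30979.6 ± 153.7) and Junb (-0.61 ± 0.12). Il6ra did not pass (-0.09, limma adjusted p = 0.507). Of 26 suppressive function genes, 4 rose, 5 fell and 17 did not pass, and 7 rose and 9 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.888). Ncf1, an NADPH oxidase subunit, rose 1.95-fold and Cd244, a receptor used as a marker of these cells, fell 2.79-fold from 7236.9 ± 912.7 to 2644.3 ± 733.8 (limma adjusted p = 8.3e-05). Cd274 (1481.8 ± 84.4 and 1100.6 ± 113.8, limma adjusted p = 0.106) did not pass, and gave 0.0247 when the PMN-MDSC libraries were fitted alone. Arg1 (0 and 1.5) and Nos2 (4.6 and 2.8) were under the minimum level for testing. Of 23 myeloid transcription factors, 2 rose, 2 fell and 19 did not pass, with the same counts adjusted over the list alone (median -0.11, camera adjusted p = 0.598). Zeb2 fell 2.1-fold from 3612.2 ± 552.0 to 1705.5 ± 140.0 (-1.07 ± 0.11, limma adjusted p = 7.9e-05) and passed whichever library was left out. The other 3 failed in 4 or 5 of 12 such fits, with the highest limma adjusted p at 0.0776 for Cebpe (without Ctrl replicate 003), 0.117 for Id2 and 0.0881 for Klf2 (both without Ctrl replicate 002). Of 28 monocyte genes, 3 rose, 2 fell and 23 did not pass, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.48). Besides Ly6c2, which rose, Csf1r, the M-CSF receptor, fell (-0.49 ± 0.10).

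**Figure D3:**
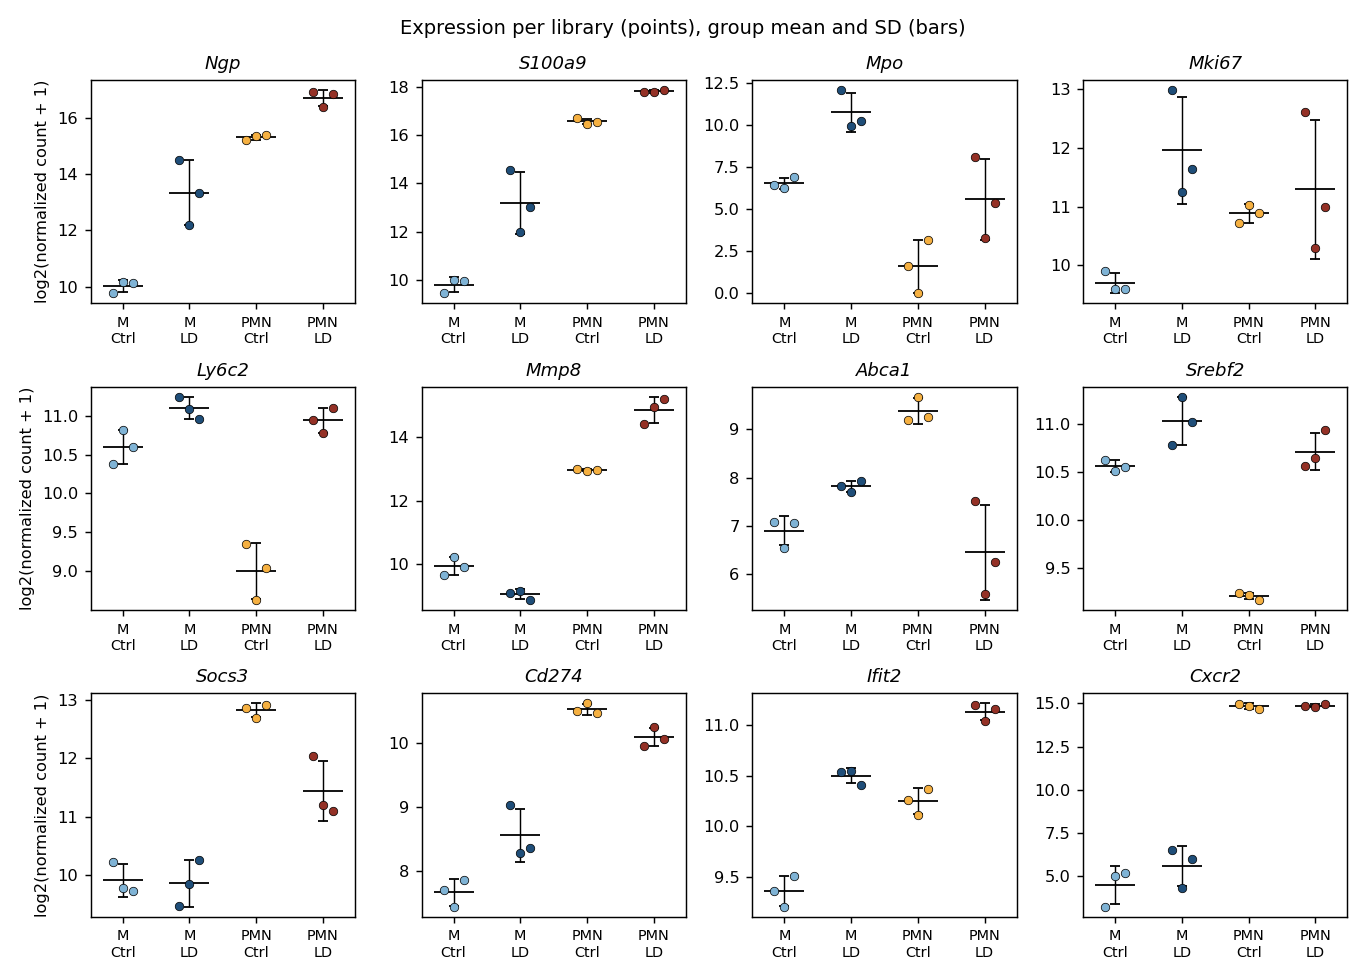
Expression of 12 genes as log2(normalized count + 1) per library (points), with the group mean (long bar) and SD (whiskers) of 3 libraries per group, M-MDSC in blue and PMN-MDSC in orange and red. Ngp and Mpo rose in both populations, Ly6c2 and Mmp8 rose in PMN-MDSC, and Cxcr2 read 29541.5 and 30074.1 normalized counts in PMN-MDSC Ctrl and LD.

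Interferon-stimulated genes rose in PMN-MDSC, with 15 of 32 higher and 17 not passing, and 17 higher and 2 lower adjusted over the list alone (median 0.40, camera adjusted p = 3.2e-08, and adjusted p = 0.464 with an estimated correlation). Ifit2 rose from 1220.9 ± 109.0 to 2245.2 ± 127.3 (0.88 ± 0.10, limma adjusted p = 1.3e-04), Zbp1, a nucleic acid sensor, rose 1.78-fold and Cmpk2 1.93-fold. Of 14 MHC class I genes, 4 rose and 10 did not pass, with 4 adjusted over the list alone (median 0.22, camera adjusted p = 0.0066, and adjusted p = 0.464 with an estimated correlation). Without Ctrl replicate 003 none of the 4 passed (B2m 0.0679, H2-K1 0.178, Psmb8 0.131 and Psmb10 0.124), and all but B2m also failed without other libraries. Of 14 MHC class II and costimulation genes, 3 fell (H2-Ob, H2-Eb2 and Ciita) and 11 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.0886, and 0.0391 without a minimum level). H2-Ob fell from 19.2 to 3.3 (-2.31 ± 0.50), while Ciita and H2-Eb2 no longer passed in 9 and 11 of 12 fits that left out 1 library (highest limma adjusted p 0.189 and 0.149, each without Ctrl replicate 003). Of 18 interferon gamma-inducible genes, 2 rose, 1 fell and 15 did not pass (camera adjusted p = 0.168, and 0.048 without a minimum level). Of 20 inflammatory cytokines and NF-kappaB targets, 2 rose, 1 fell and 17 did not pass (0.947), and of 23 chemotaxis and adhesion genes, 1 rose (S1pr4, 492 ± 40.8 to 1000 ± 211.3) and 22 did not pass (0.988). For these last 3 lists the counts adjusted over the list alone were the same.

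Cell cycle lists differed less clearly in PMN-MDSC. Limma called 0 of 25 cell division genes (1 at an unadjusted p under 0.05, 0 by edgeR, 0 by DESeq2) and 0 of 27 DNA replication genes (3 at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2), with camera adjusted p of 0.266 and 0.0542. On edgeR statistics both lists passed (0.00774 and 0.00173), and on DESeq2 statistics as well (0.0465 and 0.00717). DNA replication also passed without any 1 of 5 libraries (M-MDSC LD replicates 001 and 002, PMN-MDSC Ctrl replicate 002 and PMN-MDSC LD replicates 002 and 003), and under 8 other alternatives, among them a block by replicate number (0.0237) or by presumed animal (0.0485) and the PMN-MDSC libraries fitted alone (0.0472). Mki67 read 1895.5 ± 204.5 in Ctrl and 3175.8 ± 2682.8 in LD (0.41, limma adjusted p = 0.585, and -0.24 without LD replicate 001). Of 14 replication-dependent histones, 2 rose and 12 did not pass, with 2 adjusted over the list alone (median 0.60, camera adjusted p = 0.0236, and adjusted p = 0.759 with an estimated correlation). The list was lost without Ctrl replicate 001 (0.0516), Ctrl replicate 003 (0.118) or LD replicate 001 (0.533, where the median was 0.03). Sample weights (median 0.22, camera adjusted p = 0.251), robust empirical Bayes (0.0535) and leaving out both LD libraries numbered 001 (0.442) ended the call too. Of 13 granulocyte-monocyte progenitor genes, 1 rose (Lmo2, 0.57) and 12 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.072). The list passed when the PMN-MDSC libraries were fitted alone (0.00911), by edgeR (0.0263) and with a pseudocount of 8 (0.0421), and it also passed without any 1 of M-MDSC LD replicates 001 and 002, PMN-MDSC Ctrl replicate 003 and PMN-MDSC LD replicate 002. Of 19 p53 targets, 3 rose, 2 fell and 14 did not pass (0.988), with the same counts adjusted over the list alone. Without Ctrl replicate 003, Cdkn1a (limma adjusted p = 0.104) and Ccng1 (0.0867), which rose, no longer passed. Nor did Btg2 (0.158) and Aen (0.0583), which fell. Of 24 ribosome biogenesis genes, 1 fell and 23 did not pass (0.37), with 0 adjusted over the list alone. Of 22 unfolded protein response genes, Ppp1r15a and Atf3 fell and 20 did not pass (0.168), with 1 higher and 3 lower adjusted over the list alone. This list passed when the PMN-MDSC libraries were fitted alone (camera adjusted p = 0.0472).

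Markers of other cells and of RNA quality in PMN-MDSC did not pass as lists at the minimum level used. Malat1, a nuclear RNA, made up 3.6 ± 0.66% of reads in PMN-MDSC Ctrl and 1.91 ± 0.091% in LD (-0.84, limma adjusted p = 0.0217), and no longer passed without Ctrl replicate 002 (0.0808) or Ctrl replicate 003 (0.0937). Rn45s took 1.87% to 2.34% of reads in Ctrl and 2.48% to 3.82% in LD, without overlap, the opposite direction to M-MDSC. Of 8 nuclear and noncoding genes, 1 rose, 3 fell and 4 did not pass, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.48). Of the plasma cell list 2 of 4 members fell (0.189), of the B cell list 1 rose and 1 fell of 5 (0.888), of the dendritic cell list 2 of 12 fell (0.133), and of the macrophage list 1 of 16 fell (0.48). Each of these member calls was lost without at least 1 library. Examples are Cd22 (limma adjusted p = 0.103 without LD replicate 003), Prdm1 (0.0893 without Ctrl replicate 001) and Apoe (0.0781 without LD replicate 003). Without a minimum level, which lets in genes of low counts, the B cell list has a median of -2.73 (camera adjusted p = 7.3e-06). The T cell (0.37), NK cell (0.71), erythroid (0.899), platelet and megakaryocyte (0.988), eosinophil (0.979), basophil and mast cell (0.899), melanoma (0.697), and stroma and endothelium (0.888) lists did not pass either. Among their members, 1 NK cell gene and 1 platelet and megakaryocyte gene fell, and 1 eosinophil gene rose.

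Whether the populations responded differently was tested as the LD change in M-MDSC minus that in PMN-MDSC. Abca1 lay toward M-MDSC (difference 3.83 ± 0.50, limma adjusted p = 0.00225), Irg1 (2.65, 0.00826) and the integrin gene Itgax (1.52, 0.00561) did too, and Cd274 moved up in M-MDSC relative to PMN-MDSC (1.33 ± 0.25, 0.0132). Mmp8 moved the other way (-2.78 ± 0.25, limma adjusted p = 1.7e-04), falling in M-MDSC and rising in PMN-MDSC, as did Ly6c2 (-1.44 ± 0.23, 0.00724) and Srebf2 (-1.04, 0.00849). These 7 passed whichever library was left out. S100a8 (1.91, limma adjusted p = 0.116), S100a9 (2.14, 0.0724) and Mki67 (1.85, 0.157) did not pass.

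The difference passed for 131 genes toward M-MDSC and 119 toward PMN-MDSC (250). This count fell to between 113 and 154 without each of 9 libraries (113 without PMN-MDSC Ctrl 002, 116 M-MDSC Ctrl 002, 121 M-MDSC Ctrl 001, 125 M-MDSC LD 003, 131 PMN-MDSC Ctrl 003, 143 PMN-MDSC LD 002, 144 M-MDSC Ctrl 003, 151 PMN-MDSC LD 003, 154 PMN-MDSC Ctrl 001) and rose to 832 without PMN-MDSC LD 001. Of 37 lists, 13 passed with the preset correlation and 0 with an estimated one. Cell division moved toward M-MDSC (median 1.99, camera adjusted p = 1.3e-09, and adjusted p = 0.424 with an estimated correlation), with 1 of 25 members past the threshold over all genes and 18 adjusted over the list alone, and a median of 2.68 without PMN-MDSC LD 001. In Ctrl, 18 cell division genes were lower in M-MDSC than in PMN-MDSC and 1 was higher (median -1.53, camera adjusted p = 0.0831). In LD, 1 was lower and 2 were higher (median 0.66, camera adjusted p = 0.357). The move thus started from a lower level in M-MDSC, and in LD the list did not differ between populations past the threshold. MHC class II and costimulation moved toward M-MDSC too (median 1.27, camera adjusted p = 5.0e-04, and adjusted p = 0.342 with an estimated correlation), with 3 of 14 members, H2-Eb1, H2-Eb2 and H2-Ob, and 7 adjusted over the list alone. Cholesterol synthesis moved toward PMN-MDSC (median -0.53, camera adjusted p = 7.8e-04, and adjusted p = 0.272 with an estimated correlation), with 3 of 19 members, Srebf2 and Sc4mol among them, and 4 adjusted over the list alone. The secondary and tertiary granule list passed in both populations at the preset correlation and in neither with an estimated one (0.072 and 0.268). Its changes did not pass the test of a difference (median -0.10, mean 0.28, camera adjusted p = 0.45), with 3 members toward M-MDSC and 4 toward PMN-MDSC.

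Whether the same genes changed in both populations was tested by their overlap. Of the genes that rose, 53 rose in both, against 20.3 for independent lists (odds ratio 3.12, 95% interval 2.25 to 4.27, Fisher's exact test, two-sided, p = 6.7e-11). Of the genes that fell, 18 fell in both, against 4.4 (odds ratio 5.78, 3.06 to 10.6, Fisher's exact test, p = 1.2e-07). Genes are not independent of one another, so these p-values are too small to an unknown degree. Both comparisons also share 1 estimate of the spread per gene, so genes of small spread pass more easily in both. The overlap of unrelated changes would then lie above the expected counts, and the odds ratios are too high to an unknown degree. The granule genes Ltf (3.56 in M-MDSC and 1.29 in PMN-MDSC), Ngp (3.32 and 1.39) and Lcn2 (2.83 and 1.42), the regulator Cebpe and the interferon-stimulated Ifit1, Ifit2 and Ifit3 were among those that rose in both. Adam19, Abca9, Arrdc4 and Igj were among those that fell in both. In PMN-MDSC the call for Igj (-3.47) was lost without Ctrl 002 (0.0884), Ctrl 003 (0.0613), LD 002 (0.0762) or LD 003 (0.0839) and its change was -4.75 without LD 001. There Cebpe was lost without Ctrl 001 (0.0594), Ctrl 002 (0.0554), Ctrl 003 (0.0776) or LD 003 (0.0677), and Itgax without Ctrl 002 (0.0601). In M-MDSC, Abca9 was lost without Ctrl 001 (0.0583) or LD 001 (0.054) and Mmp8 without Ctrl 002 (0.0524) or LD 003 (0.0546). Another 10 genes changed in opposite directions, among them Mmp8 (-0.89 and 1.88) and Itgax (0.88 and -0.63). The 71 shared genes numbered 37 without M-MDSC Ctrl 001, 41 without M-MDSC Ctrl 003, 36 without PMN-MDSC Ctrl 002, 36 without PMN-MDSC Ctrl 003 and 111 without PMN-MDSC LD 001. Across all genes tested, the changes in both populations correlated with a Pearson r of 0.246, and genes are not independent replicates.

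**Figure D4:**
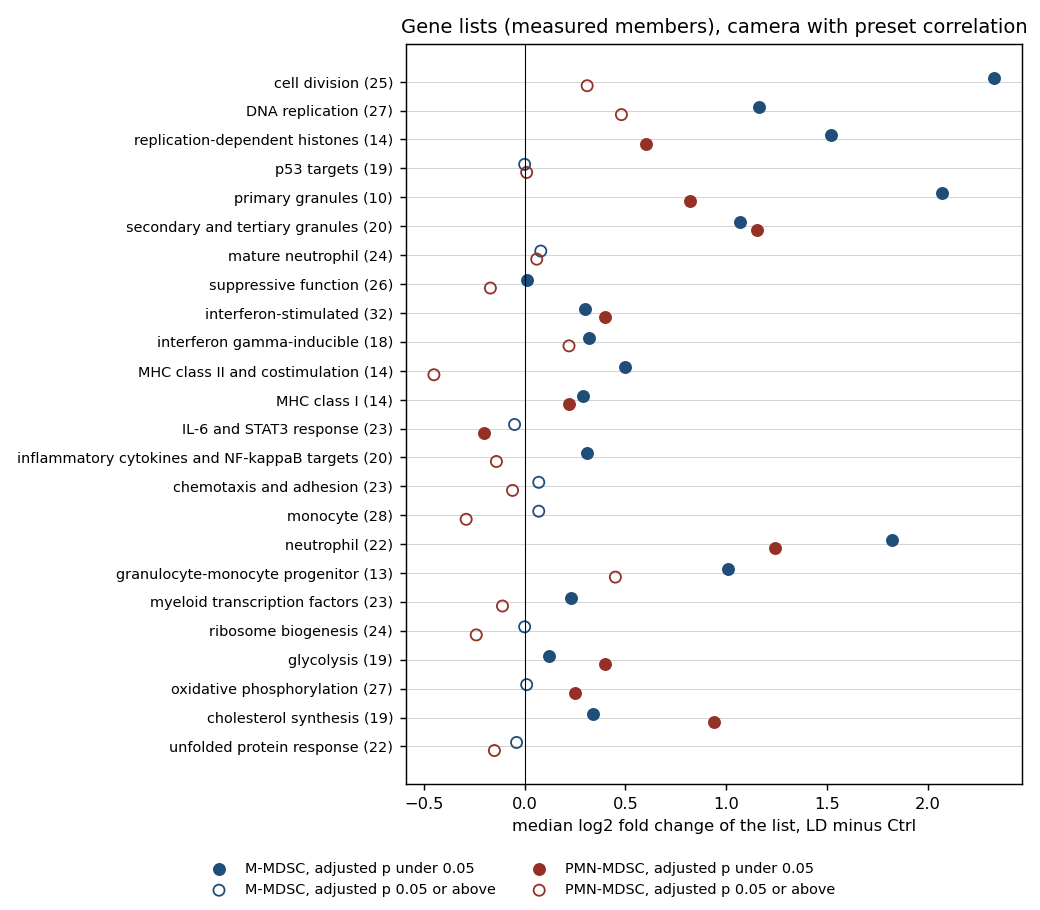
Median log2 change (LD minus Ctrl, x axis) of 24 gene lists (y axis, with the number of measured members) in M-MDSC (blue) and PMN-MDSC (red). Filled points passed camera with the preset correlation and open points did not, and cell division lies at 2.33 in M-MDSC and 0.31 in PMN-MDSC.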

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

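The tests of carried-over cells, of a single library, of weak detection and of B-lineage cells, and the counts over other splits of the samples, were chosen after the results were seen. The test of the difference between LD changes and the test of T and NK cells were not.

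The LD change differed between M-MDSC and PMN-MDSC for 44 named genes and 13 lists, by a limma test of the difference (M-MDSC minus PMN-MDSC, log2) and by camera. Of these, 16 genes and 8 lists passed whichever of the 12 libraries was left out, and 0 lists passed with an estimated correlation. Genes that passed in each of these fits included Abca1 (3.83), Irg1 (2.65), Itgax (1.52), Cd274 (1.33), H2-Q4 (0.99), Zeb2 (0.89), Slc16a3 (0.72), Mmp8 (-2.78), Sntb1 (-2.33), Acvrl1 (-2.15), Ly6c2 (-1.44), Lyz2 (-1.34), Sc4mol (-1.06), Cybb (-1.05) and Srebf2 (-1.04). The other 28 failed without at least 1 library. Those toward M-MDSC were H2-Eb2 (4.12), Cxadr (3.95), Vegfa (3.68), Inhba (3.47), Slc7a6 (3.17), H2-Ob (2.92), Ccl3 (2.90), Cd300e (2.79), Prc1 (2.60), Camp (2.42), Hdc (2.31), Ltf (2.27), Ccrl2 (2.17), H2-Eb1 (2.01), Axl (1.92), Apoe (1.74), Egr1 (1.68), Lrg1 (1.66), Socs3 (1.33), Cd244 (1), Il1rn (0.95), Oasl1 (0.87), Il10ra (0.81), Slc2a1 (0.66), Csf1r (0.61) and Cebpb (0.59). Those toward PMN-MDSC were Cobll1 (-4.42) and Thbs1 (-2.42). Some values also moved with 1 library, Cxadr to 3.34 without M-MDSC LD 001 and 4.74 without M-MDSC LD 003, Vegfa to 3.01 without M-MDSC LD 001 and 4.37 without M-MDSC LD 002, Inhba to 2.85 without M-MDSC Ctrl 002 and Cobll1 to -5.10 without PMN-MDSC Ctrl 002.

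The lists with a different change, by median, were cell division (1.99), MHC class II and costimulation (1.27), macrophage (1.11), replication-dependent histones (1.06), inflammatory cytokines and NF-kappaB targets (0.62), myeloid transcription factors (0.59), IL-6 and STAT3 response (0.18), interferon gamma-inducible (0.32), DNA replication (0.86), NK cell (2.61), basophil and mast cell (2.31, from Hdc alone), oxidative phosphorylation (-0.28) and cholesterol synthesis (-0.53). The replication-dependent histones failed without M-MDSC LD replicate 001 (camera adjusted p = 0.0518) and interferon gamma-inducible genes without M-MDSC LD replicate 003 (0.0737). DNA replication failed without M-MDSC LD 001 (0.315), PMN-MDSC LD 002 (0.322) or PMN-MDSC LD 003 (0.0977), and on edgeR (0.194) and DESeq2 (0.113) statistics. The NK cell list failed without M-MDSC Ctrl 001 (0.0779), M-MDSC LD 001 (0.0952), PMN-MDSC Ctrl 001 (0.0529), PMN-MDSC LD 002 (0.0572) or PMN-MDSC LD 003 (0.0964, where the median was 1.64), and basophil and mast cell in 8 of 12 such fits (0.13 without PMN-MDSC LD 001). Other alternatives ended both calls too, among them edgeR (0.194) and DESeq2 (0.114) for the NK cell list. For basophil and mast cell they included sample weights (0.121) and robust empirical Bayes (0.136). Without PMN-MDSC LD 001 the median was 3.57 for the NK cell list and 2.68 for cell division. Of 100 splits of the samples drawn, the real one included, 1 gave as many as the 250 genes of the difference. The highest other split gave 202, from moving 2 M-MDSC Ctrl libraries, and the next 153. Such splits also break the LD change itself, which adds to the spread or to the difference, so they do not decide by themselves. The average LD change of both populations was then first taken off each LD library. Of the same 100 splits, 1, the real one, gave as many as its 241 genes, and the highest other gave 1. The average was taken off by the real labels, and other splits mix libraries that still carry the difference, which widens their spread. These splits therefore do not exclude chance in the split of the libraries. The count of 250 also moves from 113 (without PMN-MDSC Ctrl 002) to 832 (without PMN-MDSC LD 001) when 1 library is left out. Splits of 6 libraries number 10, so the share cannot be under 0.1 for the other comparisons. Only the real split, 1 of 10, gave as many genes in each. The real counts and highest others were 335 and 1 for LD in M-MDSC, 1745 and 48 for LD in PMN-MDSC, 8407 and 0 for the populations in Ctrl, and 8323 and 0 in LD.

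Granule and cell division genes rose together in M-MDSCs of LD mice. PMN-MDSCs carried into the sort would bring their abundant transcripts in proportion, but the 50 most abundant ones rose by a median of 0.869% of their PMN-MDSC LD level (quartiles 0.101% and 2.39%), while the 283 risen genes would need a median of 22.3% (quartiles 6.68% and 93.5%). The 283 were chosen for rising, which raises their share, and 28 of the 50 rose past the threshold themselves. Mmp9 (0.0995%), Retnlg (0.0834%), Cxcr2 (0.104%) and Il1b (0.278%) stayed far below Ngp (10.8%) and Camp (19.3%). Between them, and close to one another, lay S100a9 (4.83%), S100a8 (5.27%), Lcn2 (5.89%) and Ltf (7.29%). Mpo was higher in M-MDSC LD (2190.8) than in PMN-MDSC LD (108.9), as were 93 of the 283 risen genes. These unequal shares argue against carry-over as the whole source. A small share of PMN-MDSC RNA is not excluded. Without M-MDSC LD replicate 001, which held the most granule RNA, the medians of cell division (1.77), primary granules (1.55) and secondary and tertiary granules (0.70) stayed above 0 and past the threshold at the preset correlation, which argues against 1 library as the source. With an estimated correlation these lists did not pass even with all libraries (adjusted p of 0.0802, 0.103 and 0.072). Granulocyte precursors sorted with the M-MDSCs, or a change within them, may explain the rise and cannot be told apart, since no precursor library was measured to compare with the 93 risen genes that lay above their PMN-MDSC LD level.

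Most B-lineage transcripts of low level were lower in LD. Of 24 genes of the B cell and plasma cell lists, 18 of the 21 with a Ctrl mean of at least 1 were lower in PMN-MDSC (median log2 ratio -2.34) and 15 of 20 in M-MDSC (-0.67). Igj read 184.2 in M-MDSC Ctrl and 1.1 in LD, while Cd37 rose in M-MDSC, and neither list passed camera in either population at the minimum level used. Without a minimum level, the B cell list passed in PMN-MDSC (7.3e-06) and the plasma cell list in M-MDSC (0.0497). Weaker detection of low transcripts is argued against by the median of the 21 genes in PMN-MDSC, below the lowest 1% (-0.65) of 10000 random lists with the same Ctrl levels. Among the 16 with a Ctrl mean between 5 and 50, a window that leaves out members that rose, the median was -2.50 against -0.80. In 12 of the 16, each LD library lay below all Ctrl libraries. Random lists were drawn gene by gene, while genes of these lists may move together, so their limits may be too narrow. A loss of lymphocytes of every kind is not decided. Medians of T and NK cell genes were both -0.02 in M-MDSC, and -0.66 and -0.12 in PMN-MDSC, with members moving both ways, since 5 of 10 T cell genes were lower in M-MDSC and 9 of 14 in PMN-MDSC, and 6 of 12 and 5 of 8 NK cell genes. Summed levels do not separate these kinds of cell. From Ctrl to LD they went from 161.1 to 344.7 for T cell genes in PMN-MDSC, from 116.2 to 200 and from 41 to 24 for NK cell genes in M-MDSC and PMN-MDSC, and from 724.6 to 757.5 and from 3932.1 to 3733.8 for B cell genes. Most of the B cell sums was Cd37 (377.5 to 488.8 in M-MDSC and 3246 to 3072.1 in PMN-MDSC). Bank1 (410 to 437.7) and Cd22 (103 to 206.2) came next in PMN-MDSC. The B cell sums therefore say little on the members of low level. The NK cell list in M-MDSC, of 3 genes with a median of 2.47 (camera adjusted p = 0.0134), failed with an estimated correlation (0.192), without a minimum level (median 0, 0.278), and without M-MDSC Ctrl 001 (0.058) or LD 001 (0.052). The condition set before the result, medians under 0 in both populations, was met. That at least 75% of members fall was added after the result was seen, since a median near 0 over members that move both ways decides little, and this condition alone leaves the explanation open. Fewer B-lineage cells, or less of their free RNA, in sorts labelled as over 99% pure may explain the pattern (13 of these 16 genes were lower in M-MDSC as well), but treatment and B-cell number cannot be told apart in these samples.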

How the results depend on the processing

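Sample weights by group, thinned reads and leaving out both LD libraries numbered 001 were chosen after the data were seen, and the other alternatives before. Across alternatives, gene results were the same in 11505 cases, weaker in 825, stronger in 160 and reversed in 1. List results were the same in 4084 cases, weaker in 119 and stronger in 81. Of the named genes called, 42 of 75 in M-MDSC, 43 of 94 in PMN-MDSC, 16 of 44 for the difference and 139 of 146 between populations were called in each setting.

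Leaving out 1 library gave 192 to 549 genes for LD in M-MDSC (335 with all libraries), 890 to 2162 in PMN-MDSC (1745), 113 to 832 for the difference (250) and 36 to 111 shared genes (71). Sample weights gave 976 genes in M-MDSC (646 up and 330 down, against 283 and 52), 524 for the difference and 206 shared. Weights by group gave 684 in M-MDSC (511 and 173) and 979 in PMN-MDSC. DESeq2 gave 728 in M-MDSC (555 and 173), 701 for the difference and 187 shared. Without a minimum level, where more genes share the correction, the difference had 125 genes and 43 were shared. Blocking by presumed animal gave 404 (random) and 536 (fixed) for the difference, and leaving out both LD libraries numbered 001 gave 773 and 148 shared. A change of at least 1 on the log2 scale, a stricter criterion by construction, left 446 genes in PMN-MDSC, 124 for the difference and 24 shared, and an adjusted p under 0.01 left 132, 640, 55 and 14. With an estimated correlation, lists past the threshold fell from 21 to 1 in M-MDSC, from 10 to 0 in PMN-MDSC, from 13 to 0 for the difference and from 12 to 0 between populations in Ctrl. Of lists that did not pass, neutrophil genes passed for the difference under 4 alternatives, and between populations in Ctrl cell division passed under 7 and interferon-stimulated genes under 8, fits without 1 library not counted. Except where stated, the cause was not tested.

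Upper-quartile scaling reversed Il6ra between populations in Ctrl (0.01, limma adjusted p = 0.934, against -0.29), where it shifts the median of all genes to 0.355 in Ctrl and 0.414 in LD (TMM 0.174 and edgeR 0.179 in LD). For the difference, the share of calls toward M-MDSC was 52.4%. It ran from 38.3% without PMN-MDSC Ctrl 001 to 66.9% by edgeR, with 62.8% by TMM, 39.7% without M-MDSC Ctrl 001 or PMN-MDSC Ctrl 003, and 42.4% without M-MDSC LD 003. Residuals of M-MDSC and PMN-MDSC libraries of the same treatment and number correlated across genes by -0.04, 0.05 and 0.13 in Ctrl and by 0.21, 0.12 and 0.07 in LD. In LD each was above the highest with another number (-0.07, 0.01 and 0.05) and in Ctrl that held for 003 alone, so whether numbers mark animals stays open.

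Depth limits low genes most. The lowest total was 8906045 reads, and genes under a mean of 10, among them Arg1 and Nos2, were not tested.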

Other observations

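The LXR targets were chosen after Abca1 and the cholesterol genes had been seen, with the test in PMN-MDSC written before their own values were, and the test of the difference between populations was added after the result was seen.

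Cholesterol synthesis genes rose and Abca1 fell in PMN-MDSCs of LD mice, which raised the hypothesis of lower activity of LXR, a sterol-sensing receptor that induces Abca1. Over 7 further LXR targets, the median log2 change in PMN-MDSC was -0.49 (camera p = 0.0146, and 0.0628 with an estimated correlation). Adjusted over all genes 4 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose. Abcg1 (-0.50), Mylip (-0.67), Srebf1 (-0.49) and Pltp (-1.64) fell, Smpdl3a (0.51) rose, and Lpcat3 (-0.39, limma adjusted p = 0.116) and Nr1h3 (0.12, limma adjusted p = 0.867) did not pass. In M-MDSC the median was 0.21, and the difference between populations had a median of 0.70 (camera p = 4.2e-04, and 0.0142 with an estimated correlation). Lower LXR activity is therefore 1 possible reading of the fall of Abca1 and of 4 of these targets, as a hypothesis found and tested on the same samples. The calls for these 7 targets were not tested with libraries left out. Other causes of these falls were not tested. Whether lower LXR activity bears on the rise of cholesterol synthesis genes was not tested either. Sterol content was not measured.

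Genes with at least 1 read, in libraries thinned to the same total, numbered 14568 ± 1823 in M-MDSC Ctrl, 13309 ± 406 in M-MDSC LD, 13686 ± 852 in PMN-MDSC Ctrl and 12603 ± 404 in PMN-MDSC LD (SD, n = 3). The 10 most abundant genes took 11.06% to 16.57% of the reads of a library, so the reads left for other genes were not equal.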
